A study of Homo sapiens with 4 samples.

How the data were processed

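RNA immunoprecipitation sequencing was done in the human lung adenocarcinoma cell line NCI-H1299, with 2 libraries labelled P5CS and 2 labelled input, per the labels. Total RNA was isolated with RNAiso Plus and libraries were made with a TruSeq kit, per the labels' protocols. The series title and sample titles name RIP-seq of P5CS and input, while the design text of the series speaks of LACE-seq with anti-P5CS and anti-IgG antibodies. The sample titles and the column names were followed, and no IgG library was analysed here. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10a, featureCounts and DESeq2 with the genome build hg38, without giving their settings. The annotation and the strand setting of the counting are not given in the sources used here.

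The data were a single table of all 4 libraries, with 21373 rows of which 1 repeated a gene symbol with identical values and was dropped, leaving 21372 genes. The authors deposited a whole-number count per gene and library, which was used as deposited. The deposited FPKM values, per the file headers, are the same counts divided by gene length and library total, and the gene model lengths were recovered from the quotient of the deposited counts and FPKM, where the libraries gave lengths agreeing to within 0.000137 of their median. The deposited columns of the authors' comparison, per the file headers, hold a normalised mean of counts (a signal), a log2 fold change and its standard error, a test score (stat), a p-value and an adjusted p-value. The genes that the authors marked as enriched in the deposited table are those with an unadjusted p-value under 0.05 and a fold above 1.5, a rule that matched the mark in all 21372 genes. All deposited count columns, those of the inputs included, carry the word Cyto, which no label uses, and whether a cytoplasmic fraction was used is not given in the sources used here. The input columns were matched by the word input and the replicate number. The other deposited count columns were matched to the P5CS samples by replicate number and by the absence of the word input. About 86% of deposited counts between 1 and 30 were even (86.4, 86.05, 85.76 and 86.25% per library), so both mates of a read pair appear to have been counted.

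The totals were 34730866 and 31489455 counts in P5CS IP 1 and 2 and 40911717 and 46339235 in input 1 and 2. A floor of 3 counts corresponded to 0.0864, 0.0953, 0.0733 and 0.0647 CPM in these libraries, and 95% intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries held identical values. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 22 between the IP libraries and 20.9 between the inputs. The Spearman correlation across genes was 0.966 between the IP libraries, 0.965 between the inputs and 0.918 to 0.932 between an IP and an input.

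Gene identifiers were matched to a RefSeq gene table of the assembly GRCh38.p14, which gave gene types, coordinates (1-based) and spans. The deposited table gave an identifier for 18120 genes, of which 18055 matched by it and 1 more matched by symbol. Differences between P5CS IP and input were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, glmQLFit and glmQLFTest, no replicate term) on the deposited counts. The filter kept 17304 genes and left out 4068. TMM factors were 1.102 and 1.091 for the IPs and 0.919 and 0.904 for the inputs, the common biological coefficient of variation was 0.201, and 2 residual degrees of freedom remained. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. CPM values were computed over the TMM-scaled library sizes.

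Before the data were examined, 32 gene lists were fixed. They were mitochondrially encoded mRNAs and rRNAs, cytosolic and mitochondrial ribosomal proteins, the respiratory chain, translation factors, aminoacyl-tRNA synthetases, proline, glutamate and arginine metabolism, serine and one-carbon metabolism, glycolysis, the tricarboxylic acid cycle, the proteasome, the spliceosome, nuclear-retained long non-coding RNAs, small nucleolar RNA host genes, polymerase III and other structured RNAs, small nuclear RNAs, histones, ATF4 targets, endoplasmic reticulum chaperones, heat shock, immediate early, G2/M and G1/S genes, extracellular matrix, epithelial-mesenchymal and adhesion genes, cancer signalling, RNA-binding regulators, blood and immune, fibroblast and endothelial and lung epithelial markers, and zinc finger genes. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), with an estimated correlation and with fry. Of these, 19 passed camera (15 lower, 4 higher). With an estimated correlation 0 passed camera after adjustment and 8 had an unadjusted p under 0.05. The adjusted p then ran from 0.145 to 0.472. The fry test, which does not compare a list with other genes, passed all 29. With an estimated correlation camera also uses the 2 residual degrees of freedom, so a lost call need not come from correlated members. For translation factors the estimated correlation was -0.0151, under the preset 0.01. Their unadjusted camera p still rose from 4.24e-07 to 0.0257.

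The rule for named genes was also set before the data were examined. It took ALDH18A1, the 12 genes with the largest log2 fold change in each direction (called, mean CPM of at least 5, the same direction in both same-numbered pairs, no clone names and no pseudogenes), the 6 most abundant called genes in each direction, and in each list the highest and the lowest called member, or the 2 most abundant if none was called. Single values of some list members that the rule took are not reported here, while the list counts and medians include all tested members.

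The steps were tested on simulated data. For P5CS IP against input with 200 genes changed, run on 16663 genes, 28.4% of 67 genes changed 1.5-fold, 55.2% of 67 genes changed 2-fold and 71.2% of 66 genes changed 4-fold were called, and 3 of 106 calls (2.83%) were false. In the same simulation camera gave a p under 0.05 for 2 of 50 lists without a shift. Genes were simulated independently and these lists were drawn at random, so the rate does not cover lists with correlated members. In the data the estimated correlation was 0.736 for mitochondrially encoded mRNAs, the highest of the tested lists. It was 0.219 for cytosolic ribosomal proteins and -0.0178 for matrix genes. The lowest was -0.0939, for fibroblast and endothelial markers. These estimates rest on 2 residual degrees of freedom. The data also had far more calls than the simulation (4400 higher and 4432 lower), so its share of false calls need not carry over. The alternatives tried were a replicate block, removal of a loess trend (span 0.5) of log2 fold change on gene length with and without the block, DESeq2 1.42.0 size factors, total counts, upper quartile factors, no count filter, a filter of 5 CPM in 2 samples, the DESeq2 Wald test, each library left out in turn, a minimum fold of 2, a test against a fold of 1.5, an adjusted p under 0.01, mitochondrially encoded genes left out, counts halved, and protein-coding genes only, the last 2 chosen after seeing the data. A correction for GC content was not analysed here, and alternatives for values other than counts were not needed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.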

Results

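RNA recovered with the protein P5CS was compared with input RNA in NCI-H1299, an established human lung adenocarcinoma cell line. P5CS, encoded by ALDH18A1, is a mitochondrial enzyme of proline synthesis, and the series asks which RNAs it associates with. In RNA immunoprecipitation sequencing (RIP-seq), an antibody against a protein pulls down that protein with the RNA attached to it, and the recovered RNA is sequenced beside the starting material. The data comprised 2 immunoprecipitate libraries (P5CS IP) and 2 input libraries. The gene counts summed to 34730866 and 31489455 in the P5CS IP libraries and to 40911717 and 46339235 in the inputs. No mock or IgG immunoprecipitate was analysed here, so every difference below is between the P5CS IP and the input RNA, and a gene "higher in the IP" made up a larger share of the IP RNA. No label states whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

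The input RNA was rich in short structured RNAs and mitochondrial transcripts, and the P5CS IP was poor in both. RN7SL1, the RNA of the signal recognition particle, took 19.5% ± 1.5 of input counts (SD, n = 2) and 1.69% ± 0.221 of IP counts (SD, n = 2), and RN7SL1 with its pseudogenes took 22.3% ± 1.25 and 2.06% ± 0.227. The mitochondrially encoded genes took 4.28% ± 0.257 of the input and 0.388% ± 0.0719 of the IP. RMRP, the RNA of RNase MRP, took 2.92% ± 0.39 of the input and 0.55% ± 0.14 of the IP. Protein-coding genes took 93.0% ± 0.145 of the IP against 64.8% ± 0.592 of the input, and AHNAK2, which encodes a giant scaffold protein, took 3.72% ± 0.0317 of the IP against 0.325% ± 0.00523 of the input.

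Of 17304 genes tested, 4400 were higher and 4432 were lower in the P5CS IP than in the input, and 8472 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, TMM scaling). Changes of at least 2-fold accounted for 2599 of the higher and 2464 of the lower genes, and changes of at least 8-fold for 274 and 172. The split depended on the scaling: with total counts alone, 5604 genes were higher and 3223 lower, and the median log2 fold change of all genes stood at 0.25 instead of -0.01. Where a library was left out below, 1 group held a single library and the spread came from the other group alone. In the deposited table the authors marked 4071 genes as enriched, and 386 of those had an adjusted p of 0.05 or more in the same table, the highest being 0.112. Of the 3874 genes marked by the authors in the deposited table that were tested here, 3737 were also called higher.

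**Figure D1:**
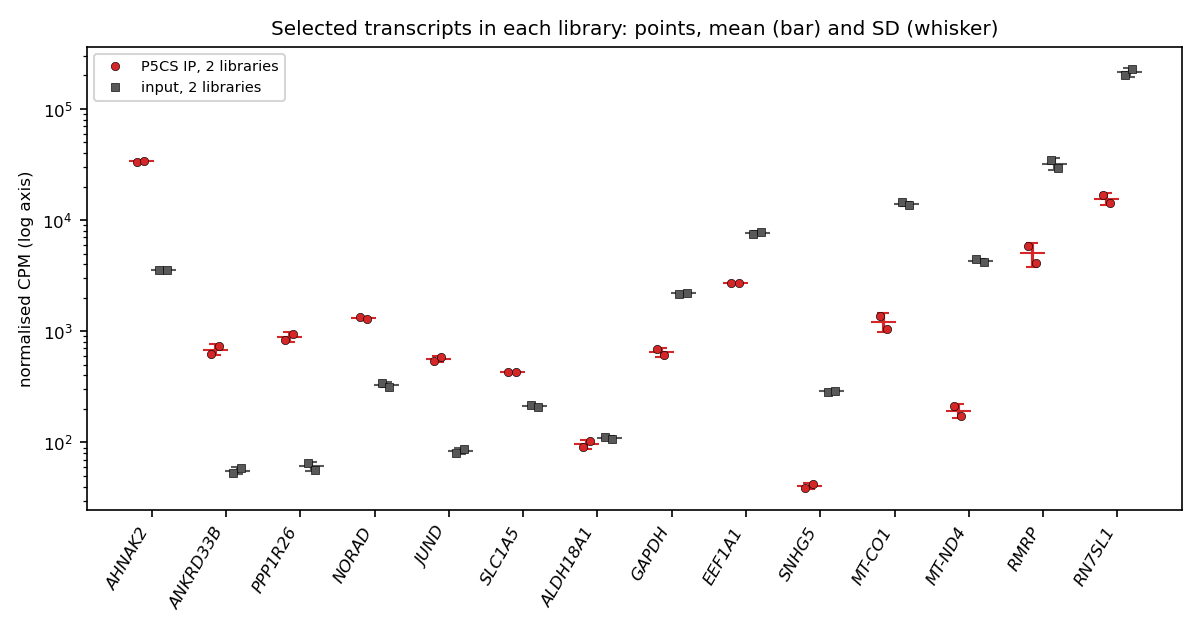
Normalised counts (CPM, log axis) of 14 transcripts in the 2 P5CS IP libraries (red circles) and the 2 input libraries (grey squares), with each group's mean (bar) and SD (whisker). AHNAK2 lay at 33905 CPM in the IP against 3562.6 in the input, RN7SL1 at 15435 against 213830, and ALDH18A1 at 96.5 against 110.1.

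The mRNA of P5CS itself was not enriched with the protein. ALDH18A1 (chromosome 10, 95605941 to 95656711, GRCh38) stood at 96.5 ± 9.11 CPM in the IP and 110.1 ± 3.72 CPM in the input (SD, n = 2 each). Its log2 fold change was -0.19 (SE 0.0962) and did not pass (adjusted p = 0.125, edgeR quasi-likelihood test, Benjamini-Hochberg), its sign turned with total-count scaling (0.07), and without the second P5CS IP library it was -0.26 (adjusted p = 0.0474 by the same edgeR test, with 1 IP library and the spread taken from the inputs alone). Among 22 tested genes of proline, glutamate and arginine metabolism, 2 were higher, 8 were lower and 12 did not pass. SLC1A5, a glutamine transporter, was higher (log2 fold change 1.02, SE 0.0743), and ARG2, a mitochondrial arginase, was lower (-1.20, SE 0.252). The list's median was -0.30 and the list did not pass (camera adjusted p = 0.0756, Benjamini-Hochberg over lists). In serine synthesis and one-carbon metabolism, 3 of 14 genes were higher and 8 lower, with MTHFD2L at -1.90 (SE 0.654). The call of MTHFD2L was lost without the second P5CS IP library (-1.64, adjusted p = 0.117), without the first input (-1.84, 0.111) and without the second input (-1.95, 0.086), all by the same edgeR test, and also with total-count scaling (-1.63) and with the length trend removed in a fit with the replicate block (-1.75). The median of that list was -0.37 (camera adjusted p = 0.129). Both lists had the same counts when adjusted over the list alone.

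Transcripts of the mitochondrial genome were among the RNAs most strongly reduced in the P5CS IP. All 13 mitochondrially encoded mRNAs were lower, with a median log2 fold change of -4.02. MT-ND4, a subunit of respiratory complex I, averaged 193.1 ± 28.3 CPM in the IP and 4311 ± 150.2 CPM in the input (SD, n = 2 each), a difference of -4.48 (SE 0.106, adjusted p = 2.18e-09, edgeR quasi-likelihood test with Benjamini-Hochberg). The smallest reduction was that of MT-ND5 (-3.22, SE 0.107). MT-CO1, MT-CO2 and MT-CO3, the mitochondrially encoded subunits of cytochrome c oxidase, stood at -3.53, -4.02 and -4.11. MT-ATP6 (-4.22), MT-ATP8 (-4.36), MT-ND2 (-4.15), MT-ND3 (-3.85), MT-ND4L (-4.45) and MT-ND6 (-3.83) were lower to a like degree. The list passed camera (adjusted p = 6.78e-09, Benjamini-Hochberg over lists) and did not pass with the correlation estimated from the data (adjusted p = 0.246 with an estimated correlation). Both mitochondrial rRNAs were lower, MT-RNR1 (-3.54) and MT-RNR2 (-1.83), and of 13 tested mitochondrial tRNAs 8 were lower and 5 did not pass, with MT-TV at -4.51 (SE 0.397) and MT-TM at -3.90 (SE 0.306). Nuclear copies of mitochondrial genes share reads with these transcripts, so the split between them is uncertain. All 13 mRNAs and both rRNAs were also lower when adjusted over the list alone.

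mRNAs of the nuclear genes that serve mitochondrial respiration and translation were lower too. Of 75 nuclear-encoded respiratory chain genes, 74 were lower and 1 did not pass, with a median log2 fold change of -1.82. The range of the called genes ran from ATP5F1A, the alpha subunit of ATP synthase (-0.58, SE 0.085), to UQCR10 of complex III (-3.07, SE 0.286). Of 75 mitochondrial ribosomal protein genes, 68 were lower, 7 did not pass and 0 were higher, with a median of -1.36. MRPS6 stood at -2.71 (SE 0.467). MRPS30 stood at -0.42 (SE 0.137), and its call ended with the length trend removed (-0.08), with total-count scaling, and without the second P5CS IP (-0.23) or the first input library (-0.31; adjusted p = 0.213 and 0.151, edgeR quasi-likelihood test, Benjamini-Hochberg). Of 21 tricarboxylic acid cycle genes, 19 were lower and 1 higher, with a median of -0.79. PDHB of the pyruvate dehydrogenase complex was lower (-1.82, SE 0.235), and OGDH was higher (0.33, SE 0.0785), a call that ended without the second input library (0.32, adjusted p = 0.0536, same edgeR test). Of 18 glycolysis genes, 14 were lower, among them GAPDH (-1.76, SE 0.0795), and 2 were higher, with hexokinase gene HK2 at 0.91 (SE 0.0929). All 4 lists passed camera, the respiratory chain at adjusted p = 2.99e-19, mitochondrial ribosomal proteins at 4.93e-16, the tricarboxylic acid cycle at 2.6e-05 and glycolysis at 0.00172 (Benjamini-Hochberg). With the correlation estimated from the data none passed (adjusted p = 0.145 with an estimated correlation for each of the respiratory chain, mitochondrial ribosomal and tricarboxylic acid cycle lists, and adjusted p = 0.246 with an estimated correlation for glycolysis). Adjusted over the list alone, 69 mitochondrial ribosomal protein genes were lower and the other 3 lists had the same counts.

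The mRNAs of the cytosolic translation machinery were depleted from the P5CS IP as well. All 76 tested cytosolic ribosomal protein genes were lower, with a median log2 fold change of -2.20 and quartiles of -2.55 and -1.90. Together these genes took 4.94% ± 0.014 of input counts and 1.37% ± 0.109 of IP counts (SD, n = 2 each). The smallest reduction was that of RPS24 (-1.04, SE 0.0852). Of 47 translation factor genes, 38 were lower and 6 higher, with a median of -0.97. EEF1A1, the elongation factor that delivers tRNA to the ribosome, was lower (-1.50, SE 0.0609), as was EIF3H (-2.08, SE 0.0913), whereas EIF4G1, the scaffold of the cap-binding complex, was higher (1.06, SE 0.0656). Of 20 cytosolic aminoacyl-tRNA synthetase genes, 15 were lower and 1 was higher, with a median of -0.44. FARSB stood at -1.43 (SE 0.185). AARS1 stood at 0.23 (SE 0.076), and its call ended with the length trend removed (0.17) and without the first (0.23) or the second input library (0.23; adjusted p = 0.148 and 0.165, edgeR quasi-likelihood test, Benjamini-Hochberg). The camera adjusted p was 5.24e-26 for ribosomal proteins, 1.37e-06 for translation factors and 0.00182 for synthetases (Benjamini-Hochberg over lists). None of these lists passed once the correlation was estimated from the data (adjusted p = 0.196 with an estimated correlation for ribosomal proteins and synthetases, and adjusted p = 0.145 with an estimated correlation for translation factors). Adjusted over the list alone, 2 synthetase genes were higher and all other counts of these lists were the same. Ribosomal protein genes have many processed pseudogenes, and reads shared with them make single values uncertain.

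Most tested members of the structured RNA, small nuclear RNA and small nucleolar RNA host gene lists were lower in the P5CS IP, but not every class with short gene models was. Of 21 tested microRNA genes, 9 were higher and 0 lower (median log2 fold change 1.41), and of 17 rRNA genes outside the mitochondrial genome 0 were called (median 0.10). The microRNA gene models had a median length of 81 nt. Reads counted there may come from longer transcripts that overlap them, and the strand of counting is not given. These values therefore need not be those of microRNAs. RN7SL1 (chromosome 14, 49586580 to 49586878) averaged 15435 ± 1900 CPM in the IP and 213830 ± 18970 CPM in the input (SD, n = 2 each), a log2 difference of -3.79 (SE 0.0897). Its pseudogenes RN7SL4P (-2.91) and RN7SL5P (-3.24) share its sequence, so reads may be split among them. RMRP stood at -2.67 (SE 0.143) and the Y RNA gene RNY1 at -2.36 (SE 0.19). Of 7 tested polymerase III and other structured RNAs, 6 were lower, with a median of -3.02. The vault RNA VTRNA1-3 had 2 counts in the IP libraries and 45 in the inputs, an input-to-IP ratio of 20.5 (95% counting interval 3.41 to 865 on halved counts of 1 and 23, since both mates of a pair appear to be counted), and a log2 fold change of -4.26 without a count filter that did not pass. Its call also ended with the length trend removed (-2.97), without the second P5CS IP (-3.36), without the first input (-3.48) and without the second input library (-4.77), at adjusted p = 0.114, 0.202, 0.299 and 0.0597 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 16 small nuclear RNAs of the spliceosomes and related particles, 14 were lower, with a median of -2.68, from RNU2-1 (-1.78, SE 0.139) to RNU6ATAC of the minor spliceosome (-4.36, SE 0.602). Of 23 small nucleolar RNA host genes, 17 were lower and 0 higher, with a median of -1.45. SNHG5 stood at -2.83 (SE 0.0898). SNHG17 stood at -0.56 (SE 0.18), and its call ended with total-count scaling and without the first P5CS IP (-0.41) or the first input library (-0.51; adjusted p = 0.146 and 0.0848, edgeR quasi-likelihood test, Benjamini-Hochberg). The camera adjusted p was 0.000231 for structured RNAs, 1.37e-06 for small nuclear RNAs and 4.08e-06 for host genes (Benjamini-Hochberg). These calls were lost with the correlation estimated from the data (adjusted p = 0.184 with an estimated correlation for structured RNAs, adjusted p = 0.246 with an estimated correlation for small nuclear RNAs, adjusted p = 0.145 with an estimated correlation for host genes). These 3 lists had the same counts when adjusted over the list alone.

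Long non-coding RNAs did not move together. NORAD, an abundant RNA that binds Pumilio proteins, rose to 1315.5 ± 26.6 CPM in the IP from 329.97 ± 16.7 CPM in the input (SD, n = 2 each), a 3.99-fold difference (log2 SE 0.0745, adjusted p = 9.88e-09, edgeR quasi-likelihood test with Benjamini-Hochberg). MALAT1, a nuclear RNA, fell by 2.51 on the log2 scale (SE 0.369) and was scarce even in the input, at 5.37 ± 0.00156 CPM (SD, n = 2). Of the 13 tested members of the nuclear-retained long non-coding RNA list, 2 were higher, 4 were lower and 7 did not pass. NORAD was its highest called member and MALAT1 its lowest. The name of the list was fixed beforehand and the location of its members, NORAD included, was not tested. Its values are therefore not a measure of nuclear RNA. The list's median was -0.28 and did not pass (camera adjusted p = 0.25), but the list passed with the length trend removed (median -0.77, adjusted p = 0.0283, camera, and adjusted p = 0.247 with an estimated correlation). The counts were the same when adjusted over the list alone.

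Other housekeeping groups were mostly lower in the P5CS IP. Of 55 replication-dependent histone genes, 51 were lower and 4 did not pass, with a median log2 fold change of -1.36. H4C3 stood at -2.27 (SE 0.0968) and the linker histone gene H1-4 at -0.52 (SE 0.0763), a call that ended with the length trend removed (0.06, adjusted p = 0.564, edgeR quasi-likelihood test, Benjamini-Hochberg). Histone genes occur in near-identical copies, so reads may be split between them. Of 30 proteasome genes, 27 were lower and 1 higher, with a median of -0.99, from PSMB6 (-1.93, SE 0.146) to PSMD2 (0.32, SE 0.0713). Of 33 core spliceosome protein genes, 21 were lower and 2 higher, with a median of -0.93, from SNRPD2 (-2.28, SE 0.119) to PRPF8 (0.51, SE 0.0694). Of 21 G2/M cell cycle genes, 14 were lower and 2 higher, with a median of -0.44. CDK1, the mitotic kinase, was lower (-1.34, SE 0.202) and the proliferation marker MKI67 was higher (0.92, SE 0.0654). The camera adjusted p was 7.7e-14 for histones, 3.87e-08 for the proteasome, 0.000187 for the spliceosome and 0.00289 for G2/M genes (Benjamini-Hochberg). Camera passed none with a correlation estimated from the data (adjusted p = 0.145 with an estimated correlation for the proteasome, adjusted p = 0.196 with an estimated correlation for histones and G2/M genes, adjusted p = 0.246 with an estimated correlation for the spliceosome). Adjusted over the list alone, 22 spliceosome genes and 17 G2/M genes were lower, and the counts of histone and proteasome genes were the same.

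**Figure D2:**
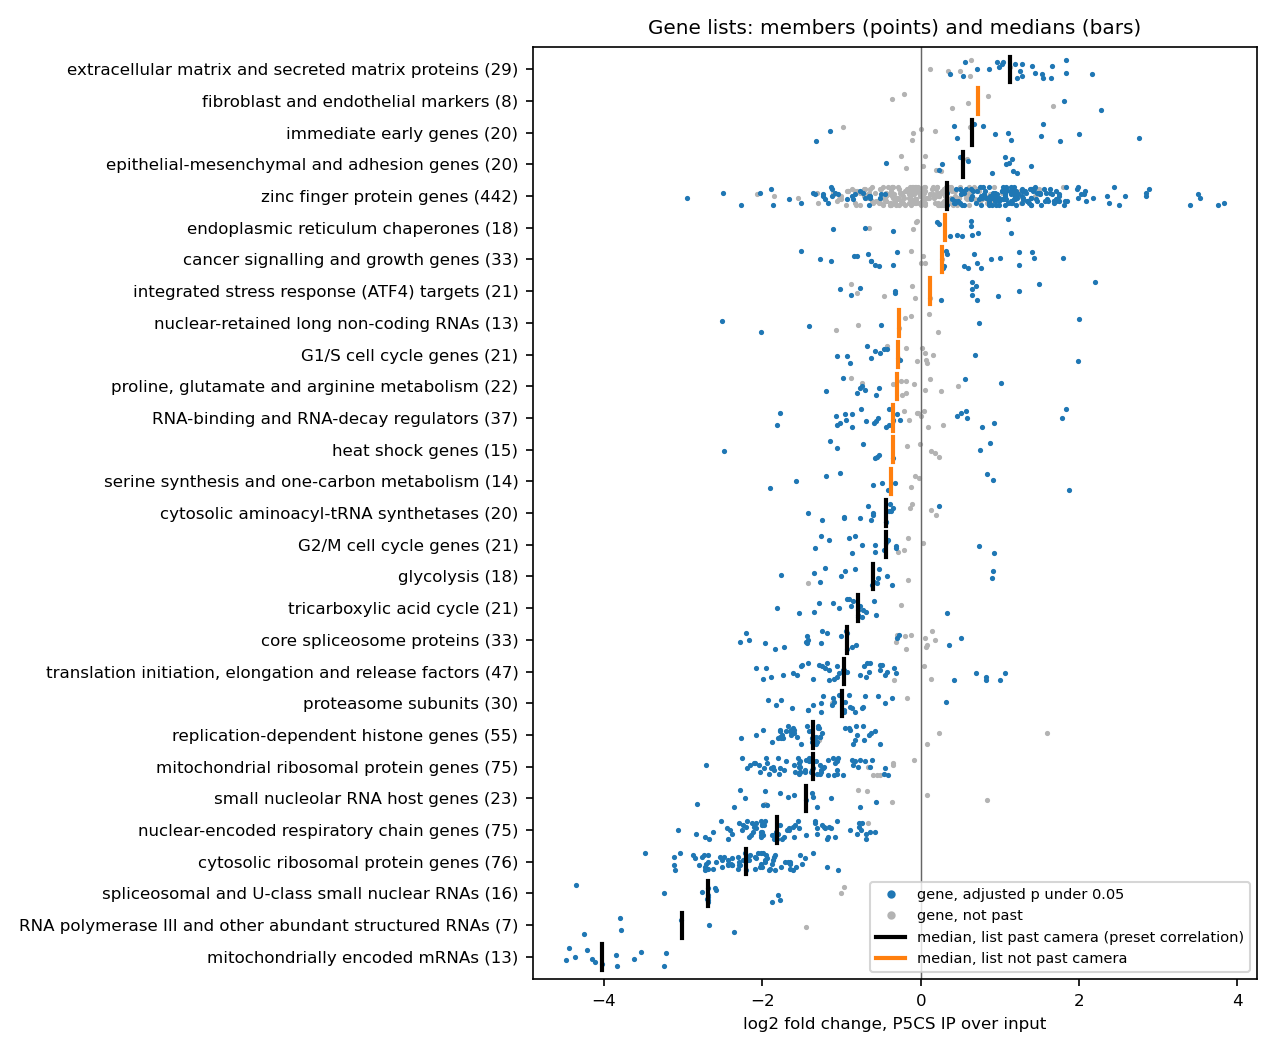
Log2 fold change, P5CS IP over input, of tested genes in the 29 gene lists with at least 3 tested members (number in brackets). Blue points passed at an adjusted p under 0.05, grey points did not, genes with 0 counts in a group were not drawn, and bars are medians, black where the list passed camera with the preset correlation. The medians ran from -4.02 for mitochondrially encoded mRNAs to 1.13 for extracellular matrix genes.

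Among the fixed lists that passed camera, extracellular matrix mRNAs had the highest median. Of 29 tested matrix genes, 23 were higher, 0 were lower and 6 did not pass, with a median log2 fold change of 1.13. The range of the called genes ran from COL6A2 (0.37, SE 0.077) to COL5A2 (2.16, SE 0.376), both collagen chains. Of 20 immediate early genes, 12 were higher and 2 lower, with a median of 0.65. JUND, a subunit of the AP-1 transcription factor, rose to 566.1 ± 31.9 CPM from 84.1 ± 5.49 CPM (SD, n = 2 each), a log2 difference of 2.75 (SE 0.0878), whereas FOSL1, another AP-1 subunit, was lower (-1.32, SE 0.096). Of 20 epithelial-mesenchymal and adhesion genes, 12 were higher and 1 was lower, with a median of 0.54. The matrix protease gene MMP14 was higher (1.40, SE 0.0965), and VIM, the intermediate filament vimentin, was the member that was lower (-0.44, SE 0.0646). Among 442 zinc finger protein genes, 160 were higher, 33 were lower and 249 did not pass, with a median of 0.33. ZNF276 had the highest value (3.83, SE 0.114). ZNF22 had the lowest called value (-2.95, SE 1.02), from 8 counts over the IP libraries, and its call ended with the replicate block (-2.81, adjusted p = 0.0728), without the first P5CS IP (-2.87, 0.115), without the second P5CS IP (-2.996, 0.102) and without the first input library (-2.08, 0.423), all by the edgeR quasi-likelihood test. The camera adjusted p was 3.28e-08 for matrix genes, 0.0129 for immediate early genes, 0.00501 for adhesion genes and 0.0017 for zinc finger genes (Benjamini-Hochberg). All of these calls were lost at a correlation estimated from the data (adjusted p = 0.145 with an estimated correlation for matrix and zinc finger genes, adjusted p = 0.213 with an estimated correlation for immediate early genes, adjusted p = 0.246 with an estimated correlation for adhesion genes). Adjusted over the list alone, 154 zinc finger genes were higher and 31 lower, and the counts of the other 3 lists were the same.

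Of the 12 named genes with the largest enrichment, 11 were protein-coding, and all averaged at most 60.96 CPM in the input. PPP1R26 (chromosome 9, 135479066 to 135488892), which encodes a regulatory subunit of protein phosphatase 1, averaged 890.6 ± 86.5 CPM in the IP and 60.96 ± 5.96 CPM in the input (SD, n = 2 each), a difference of 3.87 (SE 0.105, adjusted p = 3.07e-09, edgeR quasi-likelihood test with Benjamini-Hochberg). ANKRD33B reached 684.6 ± 79.6 CPM against 55.57 ± 4.03 CPM in the input (3.62, SE 0.105). The protocadherin PCDHA12 (4.68, SE 0.271), the zinc finger repressor SNAI3 (4.15, SE 0.296) and the sulfate transporter SLC26A1 (4.12, SE 0.166) headed the order of enrichment among called genes with a mean of at least 5 CPM. ZNF497 (3.75), the talin-related TLNRD1 (3.71), the ketone-body enzyme gene OXCT2 (3.70), NDST1-AS1 (3.69), SPRN (3.67) and the sulfotransferase gene CHST2 (3.62) followed. PCDHA12 shares its constant exons with the other genes of its cluster, OXCT2 has a close pseudogene, and NDST1-AS1 is antisense to NDST1 with the strand of counting not given in the sources used here, so these 3 values are uncertain. Of the most abundant enriched mRNAs, AHNAK2 (chromosome 14, 104937253 to 104978374) averaged 33905 ± 536.1 CPM against 3562.6 ± 16.4 CPM, a 9.52-fold difference. AHNAK (1.68, SE 0.0603), the cytolinker gene PLEC (1.42, SE 0.0802) and the integrin gene ITGA3 (1.17, SE 0.064) were higher by smaller amounts. DYNC1H1, the heavy chain of dynein (0.50, SE 0.067), and the receptor kinase gene AXL (0.23, SE 0.0607) were also called, but with the length trend removed DYNC1H1 stood at -6.0e-05 and AXL at 0.13 (adjusted p = 0.106, edgeR quasi-likelihood test, Benjamini-Hochberg), and AXL also lost its call without the first (0.23) or the second input library (0.23; adjusted p = 0.0869 and 0.0876, same edgeR test).

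Several groups held members that moved apart, and their lists did not pass. Among 33 cancer signalling and growth genes, 16 were higher and 12 lower, with STK11, the kinase LKB1, at 1.80 (SE 0.104) and a median of 0.26 (camera adjusted p = 0.444), and with the length trend removed 12 were higher and 14 lower (median 0.0031). Among 37 RNA-binding and RNA-decay regulators, 8 were higher and 20 lower, from TNRC6C of the microRNA silencing machinery (1.83, SE 0.102) to YBX1 (-1.82, SE 0.085), with a median of -0.34 (camera adjusted p = 0.0756), but the list passed with the length trend removed (median -0.54, camera adjusted p = 0.000774, and adjusted p = 0.171 with an estimated correlation). Among 21 targets of the stress response factor ATF4, 10 were higher and 5 lower, from CEBPB (2.20, SE 0.117) to PSAT1 (-1.02, SE 0.102), with a median of 0.11 (camera adjusted p = 0.362). Among 18 endoplasmic reticulum chaperone genes, 11 were higher and 3 lower, from HSPA5, the chaperone BiP (1.14, SE 0.0662), to MANF (-1.11, SE 0.162), with a median of 0.30 (camera adjusted p = 0.134), and the list passed on DESeq2 statistics (camera adjusted p = 0.0411) but not in the edgeR fit (adjusted p = 0.425 with an estimated correlation). Among 15 heat shock genes, which include the mitochondrial chaperonin genes HSPE1 and HSPD1, 2 were higher and 8 lower, from HSPA1B (0.88, SE 0.0794), which shares nearly all of its sequence with a neighbouring copy, to HSPE1 (-2.48, SE 0.329), with a median of -0.35 (camera adjusted p = 0.152). Among 21 G1/S genes, 2 were higher and 10 lower, from the chromatin assembly gene CHAF1A (1.99, SE 0.089) to CDT1 of replication licensing (-1.05, SE 0.0869), with a median of -0.29 (camera adjusted p = 0.082). Adjusted over the list alone, 21 RNA-binding regulators were lower, 6 ATF4 targets were lower and 3 heat shock genes were higher, and the other counts of these 6 lists were the same.

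Markers of other cell types were near the detection limit. Of 22 blood and immune cell markers, 2 were tested and 0 passed, CD4 at 0.532 ± 0.235 CPM in the IP and 0.619 ± 0.403 CPM in the input and CD14 at 0.715 ± 0.0232 and 0.377 ± 0.00674 CPM (SD, n = 2 each). Of 12 lung epithelial markers, 2 were tested and 0 passed, AGER (0.931 ± 0.163 and 0.939 ± 0.855 CPM) and NKX2-1 (1.02 ± 0.701 and 0.106 ± 0.15 CPM). The value of NKX2-1 (3.25, adjusted p = 0.0537, edgeR quasi-likelihood test) rested on 8 counts in the first input library and 0 in the second, and did not pass. Of 8 tested fibroblast and endothelial markers, 2 were higher, KDR (2.28, SE 0.727) and VWF (1.80, SE 0.609), both under 2 CPM, and adjusted over the list alone 0 were. The call of KDR ended without the first P5CS IP library (1.59, adjusted p = 0.328) and that of VWF with the length trend removed (1.48, adjusted p = 0.0641) and without the second P5CS IP (1.42) or the second input library (1.61; adjusted p = 0.221 and 0.0843, edgeR quasi-likelihood test, Benjamini-Hochberg). That list's median was 0.72 (camera adjusted p = 0.178).

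Enrichment in the P5CS IP rose with the length of the gene. Across genes, log2 fold change and gene model length had a Spearman correlation of 0.273 over the 17304 tested genes and 0.337 over 13201 protein-coding genes (genes are not independent replicates). Of 711 genes with models of up to 500 nt, 8.16% were higher and 34.7% were lower. Of 551 genes with models over 12000 nt, 49.4% were higher and 12.5% lower. With the trend of log2 fold change on length removed, 4261 genes were higher and 4276 lower, and 3895 and 3848 of these were among the genes called without that correction. With the trend removed, the median was -3.40 for mitochondrially encoded mRNAs, -1.84 for cytosolic ribosomal protein genes, -0.71 for histone genes and 0.80 for matrix genes, and these 4 lists still passed camera with the preset correlation. None of the 4 passed in that fit with the correlation estimated from the data (adjusted p = 0.259 with an estimated correlation for mitochondrially encoded mRNAs, adjusted p = 0.18 with an estimated correlation for ribosomal proteins, adjusted p = 0.247 with an estimated correlation for histones and adjusted p = 0.161 with an estimated correlation for matrix genes). The lists of the shortest RNAs moved most, small nuclear RNAs to a median of -1.56 with 12 of 16 lower and structured RNAs to -1.81 with 5 of 7 lower (camera adjusted p = 0.000376 and 0.00239, adjusted p = 0.302 with an estimated correlation and adjusted p = 0.18 with an estimated correlation).

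**Figure D3:**
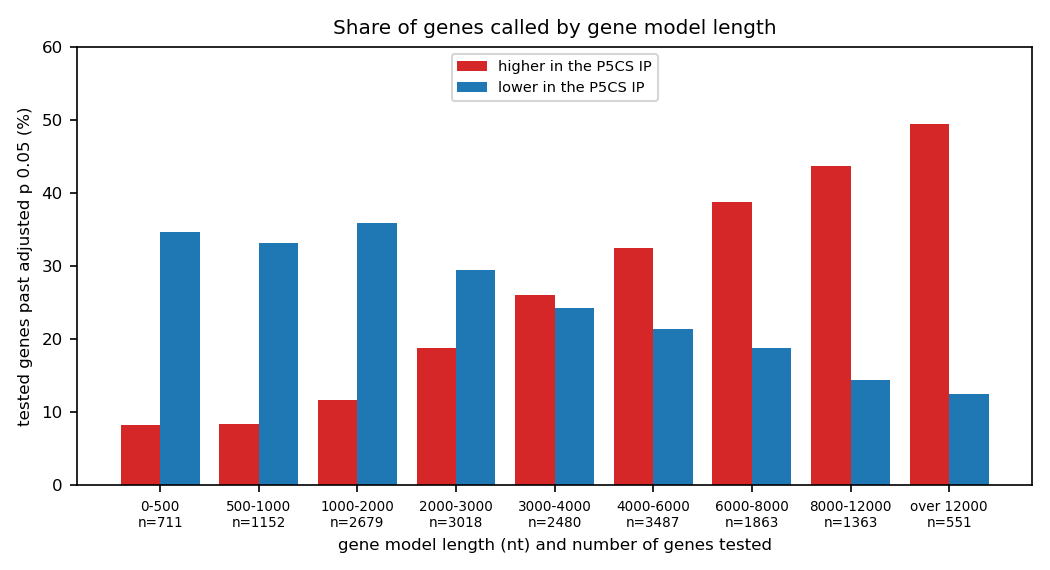
Percent of tested genes called higher (red) or lower (blue) in the P5CS IP than in the input, by gene model length in nucleotides, with the number of genes tested in each class (n). The share called higher ran from 8.16% in the shortest class to 49.4% in the longest, and the share called lower from 34.7% to 12.5%.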

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

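Only the halved counts and the restriction to protein-coding genes were chosen after seeing the data, and neither moved a count of calls or of lists past 1.5 times. The numbers of genes called higher and lower (4400 and 4432) stayed within 1.5 times under every other scaling, filter and test of the same threshold, but fell to 2599 and 2464 with a fold of at least 2 and to 2772 and 2576 in a test against a fold of 1.5, as a narrower criterion must. Leaving out each library in turn gave 4002 to 4135 genes higher and 3834 to 4244 lower, with 1 group at a single library and the spread from the other. With the replicate block 4449 genes were higher and 4487 lower and 19 lists passed. Same-numbered libraries did not deviate together (correlation of deviations across genes -0.00677), so the numbers give no ground for pairing, although each input column is named after the IP of the same number. Of the 29 lists, 19 passed in the analysis as reported. Under the other alternatives that kept all gene types, 19 to 21 of 28 to 31 tested lists passed. With mitochondrially encoded genes left out 18 of 28 passed, and with protein-coding genes only 15 of 25 passed. With camera at an estimated correlation 0 passed, and with fry 29 passed. The estimated form changes the correlation and also uses the 2 residual degrees of freedom, while fry asks another question. The loss of all calls in the estimated form therefore need not come from correlated members. No list median changed sign under any alternative. Of 98 named genes, 82 kept their direction and their side of the threshold under every alternative run on single genes, which leaves out the fold and stricter p thresholds. Direction turned in 5 of them: ALDH18A1 with total counts (0.0748), DYNC1H1 with the length trend removed (-6.0e-05), H1-4 with the length trend removed (0.0590) and the same with the replicate block (0.0674), CD4 with total counts (0.0419) and with libraries left out in turn (-0.76 to 0.66), and AGER, which was not called, with the replicate block (0.31), the length trend removed (0.33), both (0.64), DESeq2 size factors (0.011), total counts (0.25), the DESeq2 Wald test (0.0092), halved counts (0.0052), protein-coding genes only (9.4e-04) and libraries left out in turn (-0.72 to 1.47). CD4 and AGER averaged under 1 CPM in each group. The cause was not tested for any of these. NKX2-1, with 8 counts over the inputs, passed with total counts, the DESeq2 Wald test, halved counts and protein-coding genes only, and without the first P5CS IP; without the first input its only input count was 0, so that fit gives no estimate.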

Other observations

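The 18 gene families looked at outside the fixed lists were chosen after the results were seen, so no test is given for them, only counts of called genes and median log2 fold changes. Over all 17304 tested genes, 25.4% were higher and 25.6% lower. Of 52 tested clustered protocadherin genes, 43 were higher in the P5CS IP and 0 lower (median 1.96, and 1.79 with the length trend removed). The coding members encode neuronal-type adhesion molecules. The pseudogenes PCDHB18P, PCDHGB8P and PCDHGB9P were among those tested and were not called. Those of the alpha and gamma clusters share constant exons, so their reads cannot be assigned to single members with certainty. Of 20 carbohydrate and heparan sulfate sulfotransferase genes, among them the pseudogene HS6ST1P1, 15 were higher and 0 lower (median 1.5, and 1.35 with the length trend removed). Other sulfotransferases were not looked at as a family. Of 9 frizzled receptor genes, 7 were higher (median 1.86, and 1.84 with the length trend removed). All 5 tested KMT2 histone methyltransferase genes were higher (median 0.98, and 0.66 with the length trend removed). Their models had a median length of 19348 nt, and 49.4% of all tested genes with models over 12000 nt were higher. Of 37 ZBTB transcription factor genes, 26 were higher and 1 lower (median 0.87, and 0.78 with the length trend removed). Other families were more mixed: of 30 HOX genes 11 were higher and 4 lower (median 0.41), of 25 integrin genes 6 were higher and 2 lower (median 0.27), and of 232 solute carrier genes 78 were higher and 41 lower (median 0.26).

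Several pseudogene families were mostly lower. Of 138 tested ribosomal protein pseudogenes, 78 were lower and 2 higher (median -1.56, and -0.83 with the length trend removed), all 7 RN7SK pseudogenes were lower (median -3.17, and -2.36 with it removed), and 8 of 11 nuclear copies of mitochondrial genes were lower (median -2.51, and -1.82 with it removed). Reads that match both a parent and its copy would give such values, and the counts cannot separate them. Small nucleolar RNA genes had a median of -1.37 over 77 tested genes, with 25 lower and 0 higher, and a median of -0.30 with the length trend removed.

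In the weighing that follows, the tests on mitochondrially encoded and ribosomal protein mRNAs and the length and intron tests on the most enriched genes were chosen only after the results were seen, and only the genomic DNA test was set before its values were seen. P5CS is a mitochondrial enzyme, and mitochondrially encoded mRNAs were lower in its immunoprecipitate, with a list median of -4.02. All count columns carry the word Cyto, and whether a cytoplasmic fraction was used is not given in the sources used here. How this result bears on the enzyme's location therefore stays uncertain. The tables argue against gene length as the whole cause, since the median was -3.40 with the length trend removed, and against the scaling of the libraries, since the highest median over 4 scalings was -3.76. Recovery of RNA independent of P5CS cannot be told apart from an effect of P5CS, because 0 mock or IgG libraries were analysed here. A lower share of mitochondrial RNA could therefore reflect the precipitation itself.

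Cytosolic ribosomal protein mRNAs were lower with a median of -2.20. Gene length is argued against as the whole cause by the median of -1.84 with the length trend removed. These mRNAs carry a terminal oligopyrimidine motif at their start, and a candidate explanation is that mRNAs with this motif are under-represented as a class. In 15 such mRNAs outside the ribosomal proteins the mean length-corrected log2 fold change was -1.29, against -0.68 in 32 other translation factors. The difference was -0.61 (two-sided permutation test, 100000 resamples, p = 0.0186), as that hypothesis predicts against these factors. This p treats genes as independent units and does not measure the spread between libraries. Lists not chosen by the motif were low too, with length-corrected medians of -1.32 for nuclear-encoded respiratory chain genes and -1.03 for mitochondrial ribosomal protein genes. The proteasome, at -0.79, was less low. The test therefore does not show that the motif sets the low mRNAs apart. Whether the class is low in any precipitate or only with P5CS stays open and was not tested.

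For the 11 protein-coding genes with the highest enrichment by the rule for named genes, genomic DNA in the IP was tested as a source. Its level was taken from genes with 0 counts in the first input library, whose 95th percentile was 0.836 FPKM in the IP. The smallest rise among the 11 genes was 4.53 FPKM. The rule picked genes with a mean of at least 5 CPM and the largest folds, which by itself favours a rise above that level. The comparison therefore cannot decide on genomic DNA. Removal of the length trend left their median at 3.74. Even genes with models over 12000 nt had a median log2 fold change of only 0.599. Genes picked for the largest folds therefore had to stay high, and the length test cannot decide on length. It shows only that the average length trend was smaller than their folds. A preference for intron-poor genes remains possible for some of them: in 36.4% of the 11 genes (TLNRD1, OXCT2, SPRN and CHST2) the gene model covered over 0.8 of the gene's span, against 4.43% of the other tested protein-coding genes (two-sided Fisher's exact test, p = 0.001), and all 588 intron-poor genes had a length-corrected median of 0.58 against -0.07 for the others (permutation test, p = 1e-04, the smallest that 10000 permutations can give). The Fisher and permutation p-values treat genes as independent units and do not measure the spread between libraries. Histone genes, which are intron-poor, went the other way, with a length-corrected median of -0.71, and without them the difference was 0.79 over 537 genes. The other 7 of the 11 genes lack this feature, and binding to P5CS was not tested apart from recovery without it.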
